A study of Mus musculus with 10 samples.

How the data were processed

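RNA of PbT-II cells, T cell receptor transgenic CD4 T cells that recognise a malaria antigen, was measured on 10 mouse microarrays. Per the labels' protocols, 1000000 PbT-II cells were transferred into B6 mice, the mice were infected with Plasmodium chabaudi, and the spleens were taken on day 7. The transferred cells carried CD45.1 and were sorted by their surface CD11a and CD49d. The groups were the CD11a high CD49d high cells (CD49d_hi, n = 3), the CD11a high CD49d low cells (CD49d_lo, n = 3) and unstimulated cells low for both proteins (naive, n = 4), which were sorted from PbT-II mice. The naive cells therefore had neither the transfer nor the infection, and these 2 differences cannot be separated. Per the labels, RNA was prepared with RNeasy columns and labelled with biotin by a 3' IVT Pico kit. The labels call the arrays of a group biological replicates and state nothing more of their origin, so that the p-values measure the spread between these samples.

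The deposited values are log2 signals of 22206 probe sets, made with RMA by the authors, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of each set. The deposited values still differed in spread, with standard deviations of 2.90 to 3.16 on single arrays. The version of RMA and its settings are not given in the sources used here. The values ran from 2.55 to 19.27 with 2 decimals, and detection calls or scanner values were not used here. A difference of 1 on this scale is a 2-fold difference of the deposited signal. How that signal relates to the amount of RNA was not tested, so fold differences of RNA may be larger or smaller. Differences of low signals can be understated where background signal remains in both groups. The number of arrays limits the precision.

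Gene names came from the platform annotation: 19572 probe sets named 1 gene symbol, none named several, and 2634 were not named there and were left out. Each of the 19505 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for 55 genes with more than 1. Genes were tested when their signal was above 4.52, the 25th percentile of all values, on at least 3 arrays. This left 15787 genes, and 3718 were left out.

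The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with a mean for each group, no covariate and default empirical Bayes moderation (7 residual and 5.02 prior degrees of freedom). Each comparison was a difference of 2 group means with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Below, a gene that rose, fell or changed passed this test, and every adjusted p of a gene comes from it. Errors of differences are standard errors of the fit, and errors of group means are standard deviations. The fit shares a common spread per gene over all 3 groups. Errors and calls between the infected subsets therefore also depend on the spread of the naive arrays. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

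The gene lists, 33 in all, were tested with limma's camera at a correlation of 0.01 between genes, which compares a list with all other genes, with the Benjamini-Hochberg adjustment over the 32 lists that held 3 or more genes tested. The estimated correlation was above 0.01 for many lists, for example 0.155 for G2/M and mitosis and 0.838 for immediate early and heat shock genes. The p-values at 0.01 are then too small, also in the alternatives that keep 0.01. With an estimated correlation the smallest camera adjusted p of any list was 0.0052 for CD49d_hi and 0.0109 for CD49d_lo against naive. It was 0.0137 for CD49d_hi against CD49d_lo. The 23 lists on T cell biology were naive and quiescence, Th1, Tfh (T follicular helper), IL-10 and Tr1 (type 1 regulatory), regulatory T cell, inhibitory receptors and exhaustion, cytotoxicity, anergy, TCR-induced early genes, memory precursor, Th2, Th17, interferon-stimulated genes, G1/S and DNA replication, G2/M and mitosis, integrins and adhesion, chemokine receptors, cytokines and TNF family ligands, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, and apoptosis and survival. The 9 lists of other cell types were B cell, plasma cell, myeloid cell, dendritic cell, erythroid, NK cell, CD8 T cell, gamma delta and NKT cell, and platelet. A list of immediate early and heat shock genes stood for cell handling. Lists share genes, so their results are not independent of each other.

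Genes named by a fixed rule were the 8 largest increases and 8 largest decreases of each comparison among genes that changed and whose arrays did not overlap between the groups, up to 3 members of each list with the strongest test, and 24 preset genes. Some other genes in the text, such as Tnf, Cd40lg, Xbp1, Mzb1 and Prf1, fall outside this rule. They are not in the counts of named genes. Unnamed loci and antigen receptor segments were left out. Of the preset genes, 20 were tested. Ebi3 lay below the filter, and others, such as Foxp3 and Tcf7, were not analysed here. The groups, the test, the lists, the naming rule and the alternatives, except those described as chosen later, were fixed before the data were examined.

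The alternatives were quantile normalization, median centring, cyclic loess, the mean of all probe sets of a gene, no filter, a filter at the 50th percentile (5.77), a mean-variance trend with robust moderation, array weights, fits of 2 groups alone, a log2 difference of at least 1, the replicate number as a block, and leaving out each of the 10 arrays. The lists were also tested with an estimated correlation, and with fry in 1 or either direction, which tests a list against no change and not against other genes. Because the infected groups share the naive arrays, the overlap of their changes was compared with 100 simulations of unchanged groups and with the 6 splits of the naive arrays into 2 and 2.

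The fit was tested on simulated data drawn with the means and spread of the real genes, with 50 genes changed at each size among 15787. At a log2 change of 1 it called 6% for CD49d_hi against naive, 8% for CD49d_lo against naive and 4% for CD49d_hi against CD49d_lo. At a log2 change of 2 it called 84%, 88% and 76%, and at 4 it called 100%, 98% and 100% in that order. No called gene had the wrong sign. Of the calls, 5%, 4.81% and 2.17% were unchanged genes. The simulated values were normal and independent between genes, with the same spread on every array, as the fit assumes. Correlated genes and arrays of unequal spread were not simulated, so these error shares need not hold for the real comparisons. Each simulation changed 200 genes, fewer than the real comparisons called, and the adjustment is stricter when fewer genes change. The shares called can therefore understate those of the real comparisons.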

Results

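Gene expression was measured in malaria-specific CD4 T cells sorted into an infected subset with high CD49d (CD49d_hi, n = 3 arrays), an infected subset with low CD49d (CD49d_lo, n = 3) and naive cells (n = 4), with 15787 genes tested. Both infected subsets were CD11a high and were taken on day 7 of Plasmodium chabaudi infection. CD11a and CD49d are integrin subunits that rise on T cells after antigen contact. The comparisons ask how each infected subset differs from naive cells and how the subsets differ from each other.

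The median signal of the arrays lay between 5.66 and 5.91 on the log2 scale, and no pair of arrays was identical. The first principal component held 50.7% of the variance and ordered the groups, with scores of -89.6 to -65.3 for naive, 26.9 to 45.8 for CD49d_lo and 55.8 to 85.4 for CD49d_hi arrays. Pearson correlations across genes, which are not independent replicates, were 0.956 to 0.982 among naive, 0.977 to 0.987 among CD49d_lo and 0.952 to 0.981 among CD49d_hi arrays. Between groups they were 0.920 to 0.952 for naive and CD49d_lo, 0.892 to 0.936 for naive and CD49d_hi, and 0.939 to 0.974 for the infected subsets. CD49d_hi replicate 2 stood apart on the second component with a score of 88.1, and its values had a standard deviation of 2.90 against up to 3.16 on other arrays. Naive replicate 1 had a similar spread, 2.90, and the lowest mean correlation of a naive array with its group, 0.960.

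**Figure D1:**
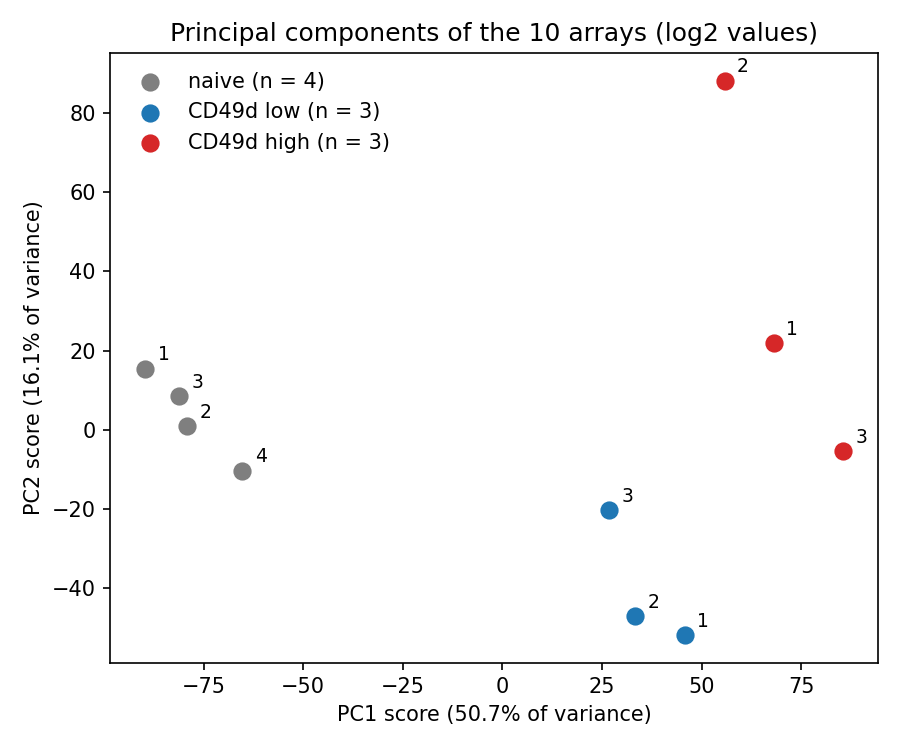
Scores of the 10 arrays on the first (x, 50.7% of variance) and second (y, 16.1%) principal components of the log2 values, one point per array with its replicate number, coloured by group. The 4 naive arrays lie below -65 on the first component and both infected subsets above 26, and CD49d_hi replicate 2 lies at 88.1 on the second.

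The transcripts of the sorted proteins were examined first. Itga4, which encodes CD49d, had a log2 signal of 14.48 ± 0.15 in CD49d_hi, 10.52 ± 0.56 in CD49d_lo and 12.49 ± 0.96 in naive cells (SD). It was higher in CD49d_hi than in CD49d_lo by 3.96 ± 0.49 (SE; limma adjusted p = 0.0011) and higher than in naive cells by 2.0 ± 0.46 (0.01). In CD49d_lo it was below naive, with -1.96 ± 0.46 (adjusted p = 0.0155), a call that ended without CD49d_lo replicate 1 (0.0934) or CD49d_lo replicate 2, with a range of 0.00154 to 0.0934 over the 10 fits that leave out 1 array. Itgb1, the integrin chain that pairs with CD49d, rose by 4.77 in CD49d_hi and by 2.86 in CD49d_lo. The difference of 1.91 between the subsets did not pass (adjusted p = 0.141), although it passed without naive replicate 1 or naive replicate 4, with a range of 0.0241 to 0.304. The Itgb1 arrays of the subsets did not overlap (14.47 to 14.65 against 12.27 to 12.9), and the naive arrays, at 8.35 to 11.61, widen the error. Itgal, which encodes CD11a, did not pass in any comparison, with 0.43 for CD49d_hi against naive (adjusted p = 0.523), 0.50 for CD49d_lo against naive (0.471) and -0.07 between the subsets (0.972). Cd4 did not pass either, with 0.42, 0.15 and 0.28 in the same order.

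In CD49d_hi cells, genes of cell killing, of the interferon gamma programme, of interleukin 10-producing cells and of cell division rose against naive cells. Gzmb, the protease granzyme B, rose by 11.01 ± 0.35 on the log2 scale (SE; adjusted p = 5.57e-09), from 6.01 ± 0.67 to 17.02 ± 0.30 (SD). Ifng, the cytokine interferon gamma, rose by 10.30 ± 0.36 (5.97e-09), Nkg7, a protein of cytotoxic granules, by 10.68 ± 0.50 (7.26e-08), and Ccl3, an inflammatory chemokine, by 10.53 ± 0.82 (3.09e-06). Ifng and Ccl3 lay among the lowest 25% of signals in naive cells. Plac8 (9.77), Il12rb2, a chain of the interleukin 12 receptor (9.18), the mitotic kinase Cdk1 (9.0) and the growth factor gene Csf1 (8.92) completed the 8 largest increases. The largest decreases were Dapl1 (-7.96 ± 0.45), the co-stimulatory receptor gene Cd226 (-7.18 ± 0.64), Atp1b1 (-6.94), Slc28a2b (-6.87), St8sia6 (-6.55), Ift80 (-6.46), Actn1 (-6.44) and Slfn5 (-6.40).

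Of 15787 genes, 2843 (18.0%) changed between CD49d_hi and naive cells, 1483 higher and 1360 lower, and 2653 of them by at least 2-fold. The share that was higher was 52.2%, and it was 48.5% after quantile normalization, 57.8% after cyclic loess and 63.0% without CD49d_hi replicate 2. The arrays of the groups did not overlap for 25.7% of the genes tested, where chance gives 5.71%. The median difference over all genes was -0.12, which cyclic loess moved to -0.0003. Without CD49d_hi replicate 2 and naive replicate 1, chosen after their spread was seen, 3046 genes changed, and 2839 when naive replicate 4 was left out as well.

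The Th1 list, genes of the interferon gamma-producing helper type, had 17 of 23 members higher in CD49d_hi cells, none lower and 6 not passing (camera adjusted p = 1.09e-19). Adjusted over the list alone, 17 were higher and 1 was lower. Tbx21, the Th1 master transcription factor, rose by 7.37 ± 0.36, Ccl4 by 7.13, Ccr2 by 4.80, Ly6c2 by 4.24 and Cxcr6 by 3.46. Cxcr3, a chemokine receptor of Th1 cells, rose by 1.40, a call that ended without CD49d_hi replicate 1 (adjusted p = 0.06, the highest of 10 fits, the lowest being 0.00727). In the cytotoxicity list 10 of 16 members rose and 1 fell (4.96e-12), or 11 and 1 adjusted over the list alone, with Gzma at 7.55 and Serpinb6b, an inhibitor of serine proteases, at 5.69. Prf1, which encodes perforin, did not pass (0.93, adjusted p = 0.415), and the member that fell was Lamp1 (-1.22). Of the cytokines and TNF family ligands, 11 of 25 rose and 1 fell (2.24e-06), or 11 and 2 adjusted over the list alone.

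Some genes of the IL-10 and Tr1, inhibitory receptor and regulatory T cell lists also rose in the CD49d_hi samples. Arrays of whole samples cannot show whether single cells expressed them together with the Th1 genes. The IL-10 and Tr1 list shares 16 of its 18 tested genes with other lists, so it is hardly a separate result. In it 14 of 18 members were higher and 1, Cd226, was lower (adjusted p = 1.78e-13), with the same numbers adjusted over the list alone. Il10, an anti-inflammatory cytokine, rose by 6.24 ± 0.31, Il21 by 8.51, the transcription factor gene Maf by 6.54 and Lag3, an inhibitory receptor, by 8.49. Il27 had -0.61 (adjusted p = 0.159). Of 14 inhibitory receptor and exhaustion genes 8 rose (8.4e-06), or 8 with 1 lower adjusted over the list alone, among them Havcr2 (4.93), Entpd1 (6.03), an ectoenzyme that degrades extracellular ATP, and Pdcd1 (4.43). In the regulatory T cell list 5 of 13 rose and 1 fell (0.00122), 6 and 1 adjusted over the list alone, led by Tnfrsf4 (6.98) and Ctla4 (6.39), with adjusted p = 0.141 with an estimated correlation. Foxp3, Nrp1 and Lrrc32 of this list were not tested, so it cannot show whether the cells were regulatory T cells.

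Genes of T follicular helper cells, which help B cells, were split in CD49d_hi cells. Il21, Icos (5.54), Il4 (5.14) and Pdcd1 rose, whereas Bcl6, their master transcription factor, had 0.23 ± 0.39 (adjusted p = 0.742) and Cxcr5, the receptor that guides cells into follicles, had 0.66 ± 0.55 (0.457). In all, 8 of 21 Tfh members were higher, 2 lower and 11 not passing, or 9 higher and 5 lower adjusted over the list alone. The list test gave an adjusted p of 0.0133, 0.0515 after quantile normalization, and adjusted p = 0.282 with an estimated correlation.

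Genes of resting T cells fell. In the naive and quiescence list 18 of 21 members were lower in CD49d_hi and none was higher (adjusted p = 1e-14), 19 lower adjusted over the list alone, with Il7r, the interleukin 7 receptor, at -5.71, the transcription factor gene Lef1 at -4.54 ± 0.31, and Ccr7, a lymph node homing receptor, at -2.36. In the memory precursor list, which shares 10 of its genes with other lists, 7 of 11 fell and 2 rose (0.00456), 8 and 2 adjusted over the list alone, with Bach2 at -4.71, Bcl2 at -3.79 and Foxo1 at -2.46.

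All 29 tested genes of G2/M and mitosis rose in CD49d_hi cells (adjusted p = 3.79e-42), 29 also adjusted over the list alone, with Mki67, a proliferation marker, at 8.57 and Ube2c at 8.04. Of 28 genes of G1/S and DNA replication 25 rose and none fell (2.71e-24), 27 adjusted over the list alone, with Uhrf1 at 5.42, Tyms at 4.91 and Mcm5 at 4.62. With an estimated correlation G2/M and mitosis gave adjusted p = 0.0052, and G1/S and DNA replication gave 0.00814. In glycolysis 11 of 16 rose and none fell (8.7e-13), 14 adjusted over the list alone, with Tpi1 at 6.60 and Slc16a3, a lactate transporter, at 3.76. In oxidative phosphorylation 12 of 25 rose and none fell (6.41e-09), 15 adjusted over the list alone, with Cox5a at 2.48 and Cox5b at 2.12, and adjusted p = 0.238 with an estimated correlation. Of the apoptosis and survival genes 7 of 17 rose and 2 fell (0.00131), 9 and 2 adjusted over the list alone, with Bcl2a1d at 5.58 and Bcl2l1, both inhibitors of cell death, at 3.75, and adjusted p = 0.127 with an estimated correlation. The count of 7 was 4 without CD49d_hi replicate 1, naive replicate 2 or naive replicate 3, and 3 without CD49d_hi replicate 3.

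Of the chemokine receptors 7 of 15 rose and 3 fell in CD49d_hi cells, the same adjusted over the list alone, with Cx3cr1 at 4.33 and Gpr183 at -3.78. The list's adjusted p of 0.0407 was 0.0515 after quantile normalization and 0.0528 without both CD49d_hi replicate 2 and naive replicate 1. It was 0.0875 without CD49d_hi replicate 2, 0.066 without naive replicate 2 and 0.0191 at its lowest, with adjusted p = 0.259 with an estimated correlation. Interferon-stimulated genes did not pass as a list (0.0514), with 3 of 25 higher and 10 lower (3 and 14 adjusted over the list alone), Usp18 at -4.45 and Gbp3 at 4.49. The list passed as lower after quantile normalization (0.0243), with no filter (0.0387), without CD49d_hi replicate 2 and naive replicate 1 (0.0261), and without these and naive replicate 4 (0.0341). Its p was 0.0226 without CD49d_hi replicate 3, 0.00732 without naive replicate 1, 0.0462 without naive replicate 3 and at most 0.152. Against no change, and not against other genes, fry in 1 direction gave the list 0.00796. The integrin and adhesion list did not pass (0.785), with 5 of 17 higher and 5 lower, 5 and 6 adjusted over the list alone, Alcam at 6.76 and Itgb3 at -3.60. The anergy list (0.679; 5 of 15 higher, 2 lower) and the Th2 list (0.913; 2 of 8 higher, 1 lower) had negative medians of -0.34 and -0.27 but positive means of 0.61 and 0.33, and the integrin list a median of 0.24 and a mean of -0.03. The TCR-induced early genes (0.336; 5 of 20 higher, 2 lower) gave 0.0243 with 8 higher without naive replicate 1, 0.64 at most, and 0.00183 without CD49d_hi replicate 2 and naive replicate 1. With an estimated correlation, 0.333 for this list, camera on all arrays gave adjusted p = 0.763. The Th17 list (0.487; 2 of 6 higher, 1 lower), cholesterol synthesis (0.771; 1 of 17 higher, 2 lower) and ribosomal proteins (0.371; none of 18 changed) did not pass.

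Markers of other cell types were measured beside these groups. The plasma cell list was higher in CD49d_hi than in naive cells, with 5 of 7 genes (adjusted p = 8.4e-06), the same adjusted over the list alone. Of its genes, 2 are also in other lists, and activated T cells also express Prdm1 (6.54), Irf4 (4.15) and Xbp1 (1.82). Jchain, the joining chain of secreted antibodies, rose by 5.62 ± 0.46 and Mzb1 by 2.02. The B cell (0.94), myeloid (0.507), dendritic cell (0.214), erythroid (0.913), NK cell (0.153), gamma delta and NKT cell (0.487) and platelet (0.189) lists did not pass. The NK cell list shares 4 of its genes with others, and its Gzma and Klrb1c (3.42) rose while Txk fell by 3.47. The dendritic cell list had 2 of 9 genes higher, among them Irf8 (3.09), which activated T cells also express. In the platelet list 2 of 5 were lower, in the B cell list 1 of 14 was lower, and in the myeloid list 1 of 13 was higher. The B cell and erythroid lists had negative medians of -0.15 and -0.13 with positive means of 0.04 and 0.01, and cyclic loess turned those medians. Without CD49d_hi replicate 2 and naive replicate 1 the platelet list gave 0.0356. Against no change, a null that leaves out the other genes, fry in 1 direction gave 0.00608 for the dendritic cell, 0.0141 for the NK cell, 0.0301 for the gamma delta and NKT cell and 0.0201 for the platelet list. Of the pair of CD8 genes, too few for a list test, Cd8b1 was lower (-2.09), with arrays that overlapped between the groups. That call ended without CD49d_hi replicate 1, CD49d_hi replicate 2, naive replicate 2 or naive replicate 3 (0.0778 at most, 0.000443 at the lowest). The cell handling list, of immediate early and heat shock genes, did not pass (0.0813; 2 of 14 lower), but gave 0.0426 after quantile normalization and 0.0341, 0.0389 and 0.00758 without naive replicates 2, 3 and 4, and 0.362 at most. With an estimated correlation, 0.838 for this list, camera on all arrays gave adjusted p = 0.75, so these lower values carry little weight.

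**Figure D2:**
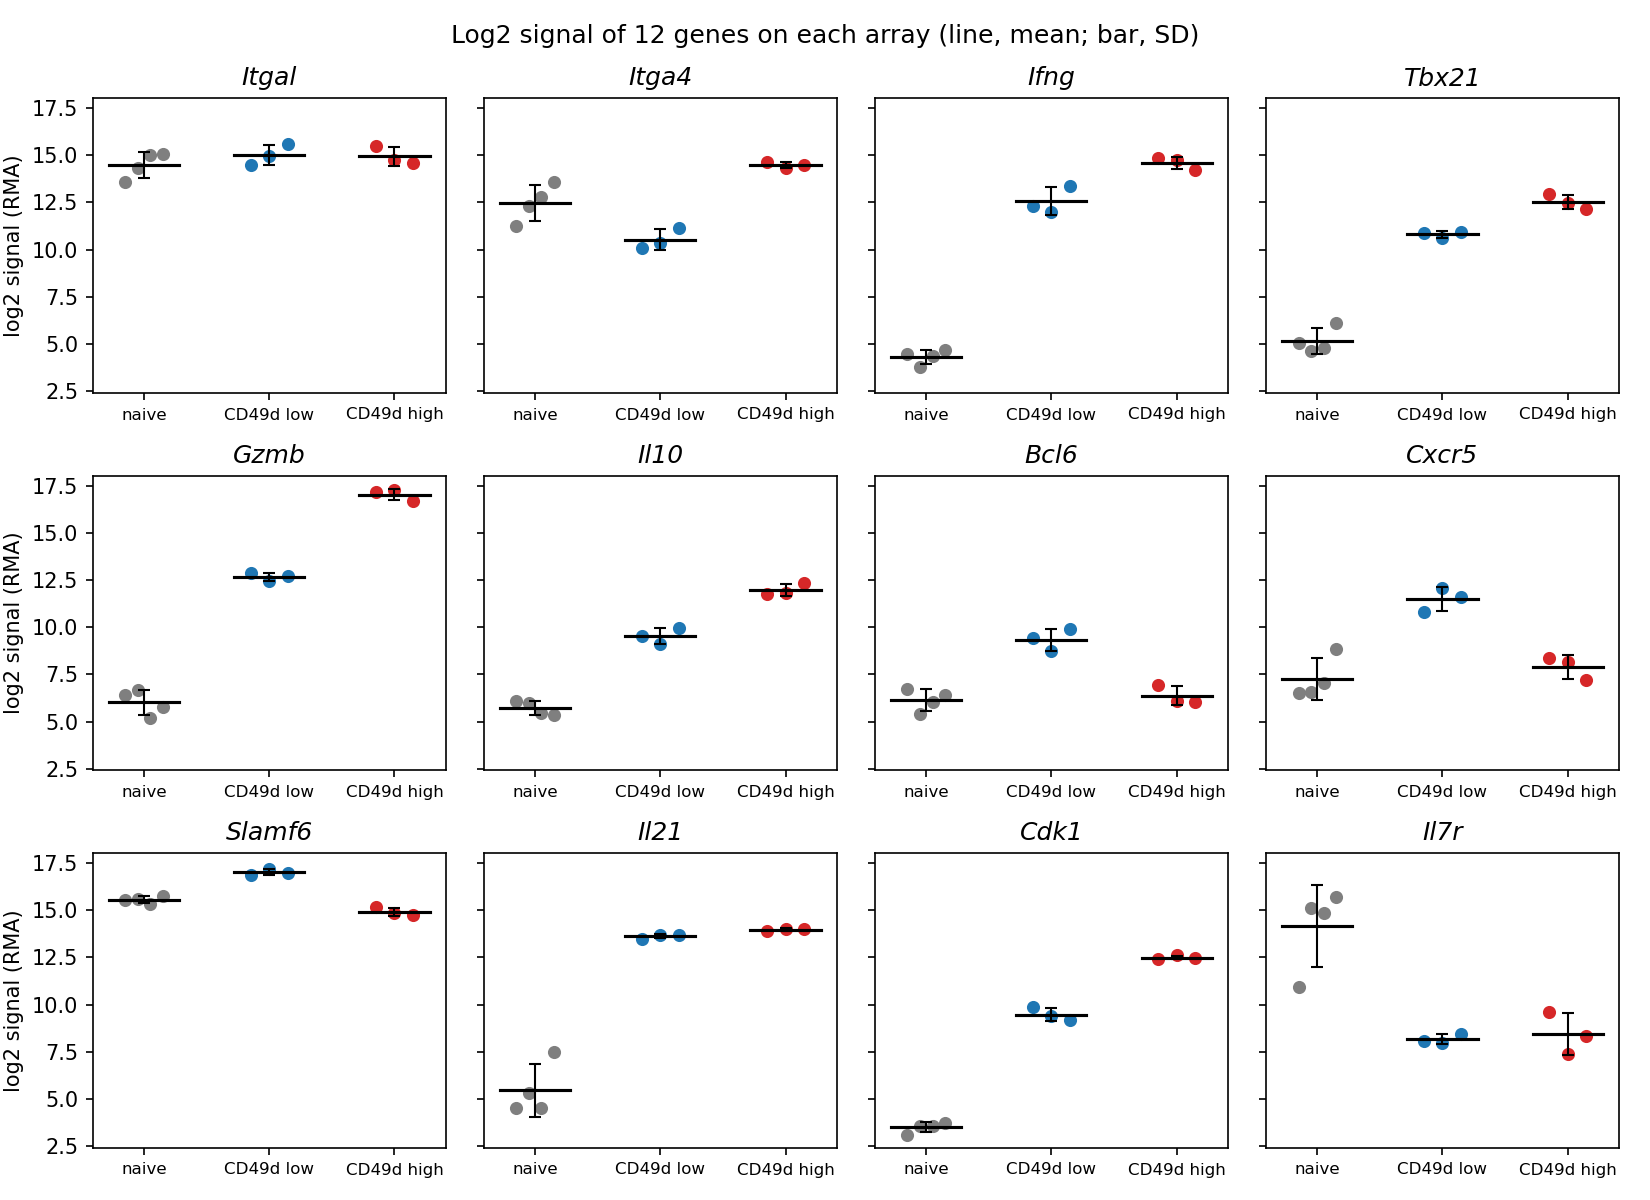
Log2 signal (y) of 12 genes on each array (points), by group (x), with the group mean (line) and standard deviation (bar). Gzmb rises from 6.01 in naive to 12.66 in CD49d_lo and 17.02 in CD49d_hi cells, whereas Bcl6 is highest in CD49d_lo cells at 9.34.

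In CD49d_lo cells, genes of cell division, of inhibitory receptors and of follicular helper cells rose against naive cells, as did the cytokine genes Ifng and Il21. Lag3 rose by 8.48 ± 0.64 (SE; adjusted p = 8.71e-06), Ifng by 8.26 ± 0.36 (2.2e-07), Il21, the cytokine with which helper T cells act on B cells, by 8.16 ± 0.58, and Klrb1c, a lectin-like receptor, by 7.90 ± 0.49. Nkg7 (7.74), Sccpdh (7.50), the inhibitory receptor gene Tigit (7.37) and Mki67 (7.34) completed the 8 largest increases. The largest decreases were Cd226 (-7.40 ± 0.64), Atp8b4 (-6.90), St8sia6 (-6.32), Il7r (-5.99 ± 0.93), Ift80 (-5.68), Irak3 (-5.65), Dapl1 (-5.52) and Sgk3 (-5.48).

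Between CD49d_lo and naive cells 1915 genes (12.1%) changed, 1256 higher and 659 lower, with 1856 changed by at least 2-fold. The share of changed genes that were higher was 65.6%, and 53.3% after quantile normalization. Arrays did not overlap for 26.3% of the genes tested, where chance gives 5.71%. The count was 907 without CD49d_lo replicate 1 and 1134 without CD49d_lo replicate 2. Array weights gave 3499 genes. Without CD49d_hi replicate 2 and naive replicate 1 the count was 2693, and 2333 without naive replicate 4 as well.

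The Tfh list had 17 of 21 members higher in CD49d_lo cells, 2 lower and 2 not passing (adjusted p = 1.18e-13), or 17 and 3 adjusted over the list alone. Bcl6 rose by 3.20 ± 0.39 (0.00022), Cxcr5 by 4.25 ± 0.55 (0.000348), Maf by 7.03, Icos by 5.82, Il4 by 4.75 and Pdcd1 by 3.61. The members that fell were Cd40lg (-2.04) and Gpr183 (-1.76). In the Th1 list 12 of 23 rose and none fell (1.22e-10), 15 adjusted over the list alone, with Il12rb2 at 7.14 and Tbx21 at 5.65. Cxcr3 rose by 1.77, whereas Cxcr6 had 0.86 (adjusted p = 0.276). Ly6c2 had 1.10 (0.13), and passed without CD49d_lo replicate 3 (0.0303, against 0.442 at most). In the cytotoxicity list 7 of 16 rose (9.78e-05), or 8 with 2 lower adjusted over the list alone, with Gzmb at 6.65 and Srgn, a granule proteoglycan, at 4.45. Cytokines and TNF family ligands had 10 of 25 higher and 1 lower (0.000192), 11 and 2 adjusted over the list alone.

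The IL-10 and Tr1 list had 11 of 18 members higher and 1 lower in CD49d_lo cells (adjusted p = 5.52e-12), 13 and 1 adjusted over the list alone, with Irf4 at 5.18, Il10 at 3.80 and Prdm1 at 3.65. Il27 had -0.42. Of 14 inhibitory receptor and exhaustion genes 8 rose and none fell (9.94e-08), 9 and 1 adjusted over the list alone. In the anergy list, genes tied to T cell unresponsiveness, 9 of 15 rose and 1 fell (0.000461), 10 and 2 adjusted over the list alone, with Egr2 at 4.33 and Nfatc1 at 3.69, and the 9 became 4 without CD49d_lo replicate 1. The regulatory T cell list passed (0.0197; 5 of 13 higher, 5 and 1 lower adjusted over the list alone), with adjusted p = 0.267 with an estimated correlation and 2 higher without CD49d_lo replicate 1. The TCR-induced early genes passed as a list (0.0414; 7 of 20 higher, 1 lower, the same adjusted over the list alone), with adjusted p = 0.549 with an estimated correlation. That p was 0.0686 after quantile normalization, and fry in 1 direction, a test against no change, gave 0.138. It was 0.0844 without CD49d_lo replicate 3, 0.0569, 0.139 and 0.125 without naive replicates 2, 3 and 4, and 0.00014 at its lowest, and the list median of 0.57 was -0.02 without naive replicate 4. The 7 became 3 without CD49d_lo replicate 1 and 4 without CD49d_lo replicate 3, naive replicate 2 or naive replicate 3.

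Resting cell genes fell and dividing cell genes rose in CD49d_lo cells as well. In the naive and quiescence list 16 of 21 fell and none rose (adjusted p = 1.15e-14), 18 adjusted over the list alone, with Actn1 at -5.16, S1pr1, the receptor for exit from lymphoid organs, at -2.99 and Ccr7 at -2.28. In the memory precursor list 6 of 11 fell and 2 rose (0.00078), 8 and 2 adjusted over the list alone. Of 29 G2/M and mitosis genes 23 rose and none fell (1.95e-30), 28 adjusted over the list alone, with Cdk1 at 5.97, Ube2c at 5.55 and Cdc20 at 4.79. Of 28 G1/S and DNA replication genes 18 rose and none fell (4.32e-18), 24 adjusted over the list alone, with Uhrf1 at 4.10, Mcm5 at 3.48 and Tyms at 3.45. In glycolysis 11 of 16 rose and none fell (4.99e-09), the same adjusted over the list alone, with Tpi1 at 5.13 and Hif1a, a transcription factor of the hypoxia response, at 3.22. The 11 became 7 without CD49d_lo replicate 1 or CD49d_lo replicate 3. Oxidative phosphorylation passed as a list (3.06e-06; 4 of 25 higher, 17 adjusted over the list alone), with adjusted p = 0.302 with an estimated correlation. Its 4 became 1 without CD49d_lo replicate 1 or CD49d_lo replicate 2 and 7 without CD49d_lo replicate 3. The apoptosis and survival list passed (0.0154; 4 of 17 higher, 1 lower, or 5 and 1 adjusted over the list alone), with adjusted p = 0.235 with an estimated correlation.

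Interferon-stimulated genes went both ways in CD49d_lo cells, with 6 of 25 higher and 9 lower, 6 and 12 adjusted over the list alone, and a lower list as a whole (adjusted p = 0.0243). The list gave adjusted p = 0.267 with an estimated correlation and 0.0836 without CD49d_lo replicate 3, with 0.0039 the lowest. Usp18 fell by 3.11 and Oas3, an antiviral enzyme, by 1.92, while Ifih1, a sensor of viral RNA, rose by 1.82. The 6 higher genes became 3 without CD49d_hi replicate 1 or naive replicate 3 and 2 without CD49d_lo replicate 1. The platelet list was lower (0.0248; 2 of 5 genes, the same adjusted over the list alone), with Itgb3, which is also in another list, at -4.24. It gave 0.0533 without CD49d_lo replicate 3, 0.0145 at the lowest, and adjusted p = 0.258 with an estimated correlation. The plasma cell list was higher (0.0184; 2 of 7 genes, Prdm1 and Irf4, or 3 adjusted over the list alone), with adjusted p = 0.0749 with an estimated correlation. The integrin list did not pass (0.141; 3 of 17 higher, 5 lower), with Alcam at 6.45 and Itga6 at -3.53, but gave 0.0469 without naive replicate 1, against 0.387 at most. Cholesterol synthesis did not pass (0.234; 1 of 17 higher, 3 lower) but gave 0.0258 without naive replicate 1, 0.0312 without CD49d_hi replicate 2 as well, and 0.429 at most without 1 array. Its 3 lower genes became 0 without CD49d_lo replicate 1 and 1 without CD49d_lo replicate 2, naive replicate 2 or naive replicate 3. The B cell list (0.0707; 1 of 14 higher, Cd22 at 2.78, and 1 lower) gave 0.0471 and the cell handling list (0.225; 1 of 14 lower) 0.0316 without naive replicate 4, against 0.19 and 0.917 at most, and the 1 lower handling gene became 3 without naive replicate 1. With an estimated correlation camera on all arrays gave adjusted p = 0.786 for the cell handling list and 0.335 for the B cell list. Cd8b1 was lower in CD49d_lo as well (-2.25, adjusted p = 0.0229), a call that ended without any 1 of the CD49d_lo arrays, naive replicate 2 or naive replicate 3 (0.000548 to 0.0757). The chemokine receptor (0.261), Th2 (0.928), Th17 (0.646), ribosomal protein (0.638), myeloid (0.464), dendritic cell (0.733), erythroid (0.696), NK cell (0.974) and gamma delta and NKT cell (0.206) lists did not pass. Against no change, and not against other genes, fry in 1 direction gave 0.0486 for the integrin list and 0.0159 for the gamma delta and NKT cell list. The Th2, dendritic cell and NK cell lists had negative medians of -0.23, -0.12 and -0.15 with positive means of 0.27, 0.08 and 0.37. Cyclic loess turned the median of the dendritic cell, NK cell, Th17 and ribosomal protein lists, and quantile normalization that of the dendritic cell list.

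Against each other, the infected subsets differed in Th1, cytotoxic and mitotic genes, higher in CD49d_hi, and in follicular helper genes, higher in CD49d_lo. Lgals3, a galactose-binding lectin, was higher in CD49d_hi by 6.68 ± 0.29 (SE; adjusted p = 4.24e-07), Gzma, the protease granzyme A, by 6.45 ± 0.71 (0.000571), Plek, a cytoskeletal protein of blood cells, by 5.55 ± 0.33 (9.11e-06), and Jchain by 5.42 ± 0.49 (0.000232). Anxa2 (5.01) and the chemokine genes Ccl3 (4.97 ± 0.87), Ccl4 (4.89 ± 0.45) and Ccl5 (4.63 ± 0.52) completed the 8 largest differences in that direction. Higher in CD49d_lo were Gpm6b (-4.88 ± 1.20), the innate receptor gene Tlr1 (-4.83 ± 0.63), the neurotrophin receptor gene Ntrk3 (-4.82 ± 0.51), Klrb1c (-4.48 ± 0.52), Parp8 (-4.10), Il6ra, the interleukin 6 receptor (-4.06 ± 0.53), Slc26a11 (-3.98) and Calcoco1 (-3.95). The call for Gpm6b (0.0468) ended in 8 of the 10 fits that leave out 1 array, all but those without naive replicate 1 or naive replicate 4, with 5.07e-05 the lowest and 0.159 the highest. That for Slc26a11 (0.0142) ended without CD49d_hi replicate 1, CD49d_hi replicate 2, CD49d_lo replicate 1 or CD49d_lo replicate 2, with a range of 0.00166 to 0.0642.

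Of 15787 genes, 532 (3.37%) differed between the subsets, 231 higher and 301 lower in CD49d_hi, each by at least 2-fold. The share that was higher in CD49d_hi was 43.4%, and 56.1% after cyclic loess. Arrays did not overlap for 19.1% of the genes tested, where chance gives 10% for 3 against 3 arrays. The count was 299 without CD49d_hi replicate 1, 255 without CD49d_lo replicate 1 and 270 without CD49d_lo replicate 2, and the genes lower in CD49d_hi were 194 without CD49d_hi replicate 2. Array weights gave 1354 genes (656 higher, 698 lower). Without CD49d_hi replicate 2 and naive replicate 1, 718 genes differed, of which 389 were higher, and 761 without naive replicate 4 as well, of which 414 were higher.

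In the Th1 list 13 of 23 members were higher in CD49d_hi and 1, Tnf, was lower (adjusted p = 3.18e-16), 16 and 1 adjusted over the list alone. With an estimated correlation this list gave adjusted p = 0.0137. The call for Tnf (-2.05) ended in 8 of the 10 fits that leave out 1 array. Ly6c2, a surface protein of Th1 cells, was higher by 3.13 (0.00329) and Havcr2 by 3.89 ± 0.38 (0.000339). Ifng was higher by 2.04 ± 0.38 (0.0117), Tbx21 by 1.72 (0.0298) and Cxcr6 by 2.60 (0.0146). The calls for Ifng (0.00484 to 0.0659) and Cxcr6 (0.00665 to 0.07) ended without CD49d_hi replicate 1, CD49d_lo replicate 1 or CD49d_lo replicate 2, and that for Tbx21 (0.00896 to 0.134) without any of these 3, CD49d_hi replicate 2 or CD49d_lo replicate 3. The 13 became 8 without CD49d_hi replicate 1, CD49d_lo replicate 1 or CD49d_lo replicate 2. In the cytotoxicity list 6 of 16 were higher and none was lower (1.38e-10), 11 and 1 adjusted over the list alone, with Gzmb at 4.36 ± 0.38 (0.000174) and Serpinb6b at 3.59. The call for Prf1 (3.10, adjusted p = 0.045) ended in 7 of the 10 fits that leave out 1 array.

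Of the 21 Tfh genes, 12 were lower in CD49d_hi than in CD49d_lo cells, none was higher and 9 did not pass (adjusted p = 2.58e-10), or 13 lower and 1 higher adjusted over the list alone. With an estimated correlation this list gave adjusted p = 0.0376. Cxcr5 differed by -3.59 ± 0.59 (0.00554), Bcl6 by -2.97 ± 0.41 (0.00215), Izumo1r, a folate receptor of T cells, by -3.13, Btla, an inhibitory receptor, by -2.51, and Slamf6, a receptor in T cell and B cell contact, by -2.10 ± 0.26 (0.00106). Il21 had 0.34 ± 0.62 (adjusted p = 0.879), Lag3 0.00 and Pdcd1 0.82, and none of these passed. The Il21 arrays did not overlap, with 13.88 to 14.02 in CD49d_hi and 13.5 to 13.7 in CD49d_lo. Its error also holds the spread of the naive arrays, 4.52 to 7.5. The 12 became 7 without CD49d_hi replicate 1 or CD49d_lo replicate 1. In the anergy list 4 of 15 were lower and none was higher (3.67e-05), 8 adjusted over the list alone, with Dgka, a kinase that dampens receptor signalling, at -3.15. The anergy count became 2 without CD49d_lo replicate 1 or CD49d_lo replicate 3.

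Among the 29 G2/M and mitosis genes 18 were higher in CD49d_hi and none was lower (adjusted p = 1.55e-32), 27 adjusted over the list alone, with Cdk1 at 3.02 ± 0.28, Ube2c at 2.49 and Birc5 at 2.49. With an estimated correlation this list gave adjusted p = 0.0137. Mki67 had 1.24 (0.402). The 18 became 10 without CD49d_hi replicate 1 and 11 without CD49d_lo replicate 1 or CD49d_lo replicate 2. In G1/S and DNA replication 4 of 28 were higher (1.38e-10; 8 adjusted over the list alone), with Rrm2 at 2.82 and Rrm1, the other subunit of ribonucleotide reductase, at 2.42, and adjusted p = 0.0656 with an estimated correlation. Those 4 became 2 without CD49d_hi replicate 1, CD49d_hi replicate 3, CD49d_lo replicate 1 or CD49d_lo replicate 2. Glycolysis was higher as a list (4.12e-05; 4 of 16 genes, 5 adjusted over the list alone), with adjusted p = 0.153 with an estimated correlation. Its 4 genes became 2 without CD49d_hi replicate 2, 1 without CD49d_hi replicate 1, CD49d_lo replicate 1 or CD49d_lo replicate 3, and 0 without CD49d_lo replicate 2.

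The cytokine list was higher in CD49d_hi (adjusted p = 0.00164; 7 of 25 genes higher and 2 lower, 8 and 4 adjusted over the list alone), with adjusted p = 0.0674 with an estimated correlation, and 4 higher without CD49d_hi replicate 1, CD49d_lo replicate 1 or CD49d_lo replicate 2. The IL-10 and Tr1 list was higher (0.0319; 3 of 18 genes, or 4 with 1 lower adjusted over the list alone), with Il10 at 2.44 ± 0.33 (0.00176), Itga2, the integrin chain CD49b, at 2.28, and Havcr2. Its test gave adjusted p = 0.287 with an estimated correlation, 0.0588 after quantile normalization, 0.0622 without CD49d_hi replicate 3, 0.0712 without CD49d_lo replicate 2 and 0.0102 at its lowest. Inhibitory receptors did not pass as a list (0.544; 2 of 14 higher and 3 lower, 3 and 4 adjusted over the list alone), with Entpd1 at 3.45 ± 0.30. The 3 lower became 1 without CD49d_hi replicate 1, CD49d_hi replicate 2, CD49d_lo replicate 1 or CD49d_lo replicate 2. The integrin list was higher (0.0138; 2 of 17 higher and 1 lower, 5 and 1 adjusted over the list alone), which includes Itga4, the transcript of the sorted protein, and gave adjusted p = 0.287 with an estimated correlation. The naive and quiescence list was lower (0.00415; 4 of 21, 6 adjusted over the list alone), with adjusted p = 0.128 with an estimated correlation. The 4 became 1 without CD49d_lo replicate 1 and 2 without CD49d_lo replicate 2. Il7r (0.27), Ccr7 (-0.08), Cxcr3 (-0.37) and Il27 (-0.19) did not pass. The chemokine receptors did not pass as a list (0.0675; 2 of 15 higher and 2 lower, 5 and 3 adjusted over the list alone), with Cx3cr1, a receptor of cytotoxic T cells, at 3.51.

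A few lists passed with 0 members past the test over all genes. Oxidative phosphorylation was higher in CD49d_hi (adjusted p = 0.0101; median 0.38), with adjusted p = 0.55 with an estimated correlation, 0.124 without CD49d_hi replicate 3, 0.323 without CD49d_lo replicate 3 and 0.000478 at the lowest. Its median ran from 0.09, without CD49d_lo replicate 3, to 0.57 in the fits that leave out 1 array. The regulatory T cell list was higher (0.0496; median 0.75; 1 higher and 1 lower adjusted over the list alone), with adjusted p = 0.311 with an estimated correlation and 0.0995 with no filter. It gave 0.0757, 0.0917, 0.0519, 0.0953 and 0.0509 without CD49d_hi replicates 1 and 3 and CD49d_lo replicates 1, 2 and 3, and 0.0281 at its lowest. The median of the list ran from 0.43, without CD49d_lo replicate 2, to 0.87 in these fits. Ribosomal proteins were lower (0.0413; median -0.25), with adjusted p = 0.493 with an estimated correlation and 0.184, 0.075, 0.159 and 0.079 without CD49d_hi replicates 1 and 3 and CD49d_lo replicates 1 and 2, against 0.00897 at the lowest. Against no change, fry in 1 direction gave 0.459 for oxidative phosphorylation, 0.248 for the regulatory T cell list, 0.0983 for ribosomal proteins, and 0.0872 for both the IL-10 and Tr1 and the integrin lists. The plasma cell list was higher (0.00254; 1 of 7 genes, Jchain, or 3 adjusted over the list alone), with adjusted p = 0.0544 with an estimated correlation. The memory precursor (0.415), TCR-induced early gene (0.157), Th2 (0.782), apoptosis and survival (0.173), cholesterol synthesis (0.343), cell handling (0.343), dendritic cell (0.121), erythroid (0.782), NK cell (0.116) and platelet (0.343) lists did not pass, nor did the interferon-stimulated (0.894) and gamma delta and NKT cell (0.743) lists. The medians of those last lists, -0.04 and -0.04, had means of the other sign, 0.01 and 0.08, and turned positive under each other scaling. The Th17 list (0.0655) gave 0.0373 after quantile normalization and 0.0285 without CD49d_hi replicate 1. The B cell list (0.0617) gave 0.0465 without CD49d_hi replicate 1 and 0.048 without naive replicate 1, and the myeloid list (0.0633) 0.00591 without CD49d_lo replicate 2. The highest values of these lists without 1 array were 0.397, 0.142 and 0.236.

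**Figure D3:**
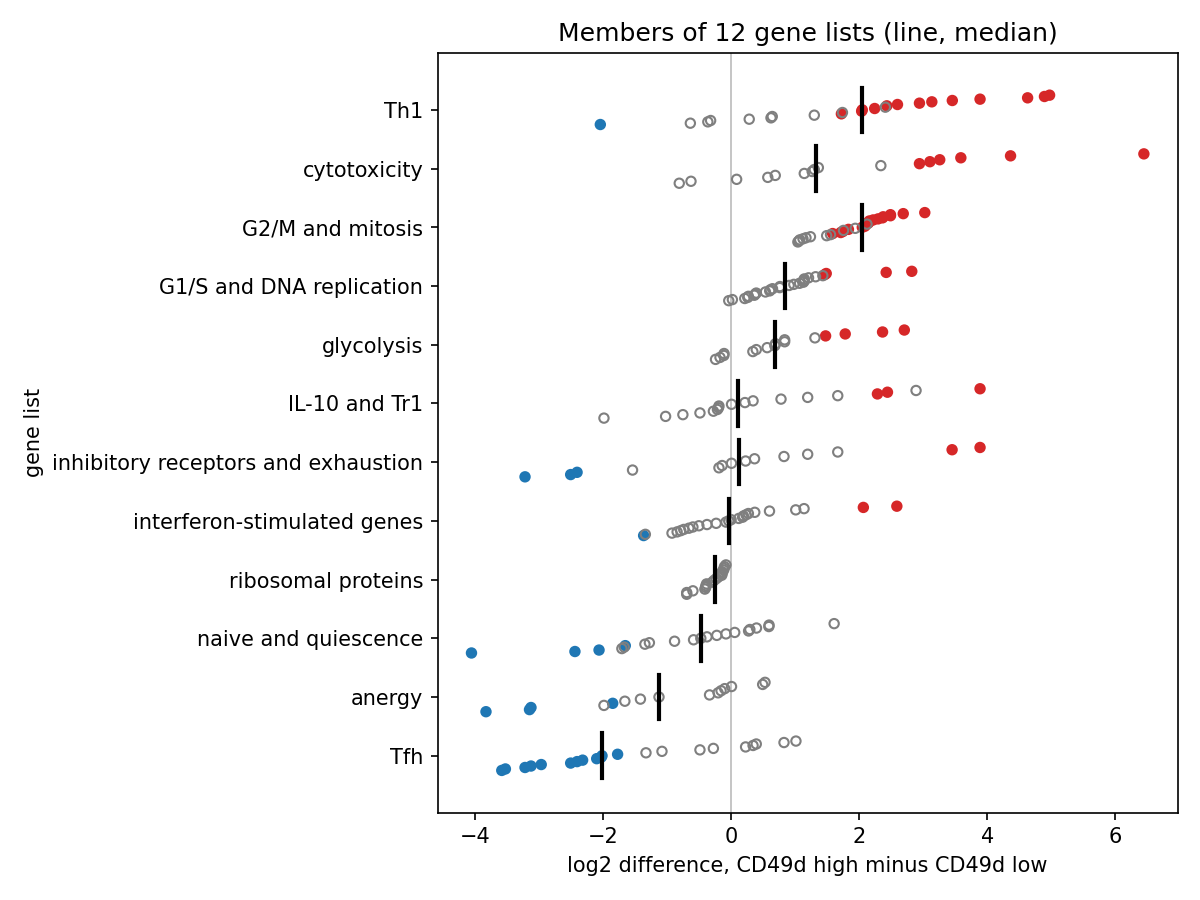
Log2 difference between CD49d_hi and CD49d_lo (x) of each tested member of 12 gene lists (y), with filled points for genes past the test, open points for the others and a line at the list median. The G2/M and Th1 medians both lie at 2.05, and the Tfh median lies at -2.02.

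The changes of both infected subsets against naive cells overlapped. Of 3367 genes that changed in either subset, 1391 changed in both, and 1376 of these in the same direction, among them Ifng, Il21, Lag3 and Mki67 (851 higher, 525 lower). Independent lists of these sizes would share 118 higher and 56.8 lower genes, and 100 simulations of unchanged groups sharing the naive arrays gave 0 called in both, as the adjustment alone would give. With the naive arrays split 2 and 2 between the comparisons, 723 to 796 genes changed in the same direction. The count of 1376 was 743 without CD49d_lo replicate 1 and 897 without CD49d_lo replicate 2. The correlation of the log2 differences across genes was 0.80 (0.677 to 0.733 with split naive arrays, 0.428 on average in the simulations). Their covariance was 0.973, against 0.0628 in the simulations, a difference of 0.910.

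A gene called in 1 subset was not always different between them. In CD49d_hi alone 1452 genes changed, and 199 of these passed the test of the difference between the subsets. In CD49d_lo alone 524 changed, and 117 of these passed it. Of the 485 genes that changed in either subset and passed that test, 346 had the larger absolute change in CD49d_hi. For 15 genes the changes were in opposite directions, with Itga4 among the 3 that were higher in CD49d_hi, and splits of the naive arrays gave 1 to 16 such genes. Without 1 array the count was 2 (CD49d_lo replicate 1), 6 (CD49d_lo replicate 2), 7 (naive replicate 2), 8 (naive replicate 4) or 9 (CD49d_hi replicate 1, CD49d_lo replicate 3 or naive replicate 3), with 17 the highest.

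**Figure D4:**
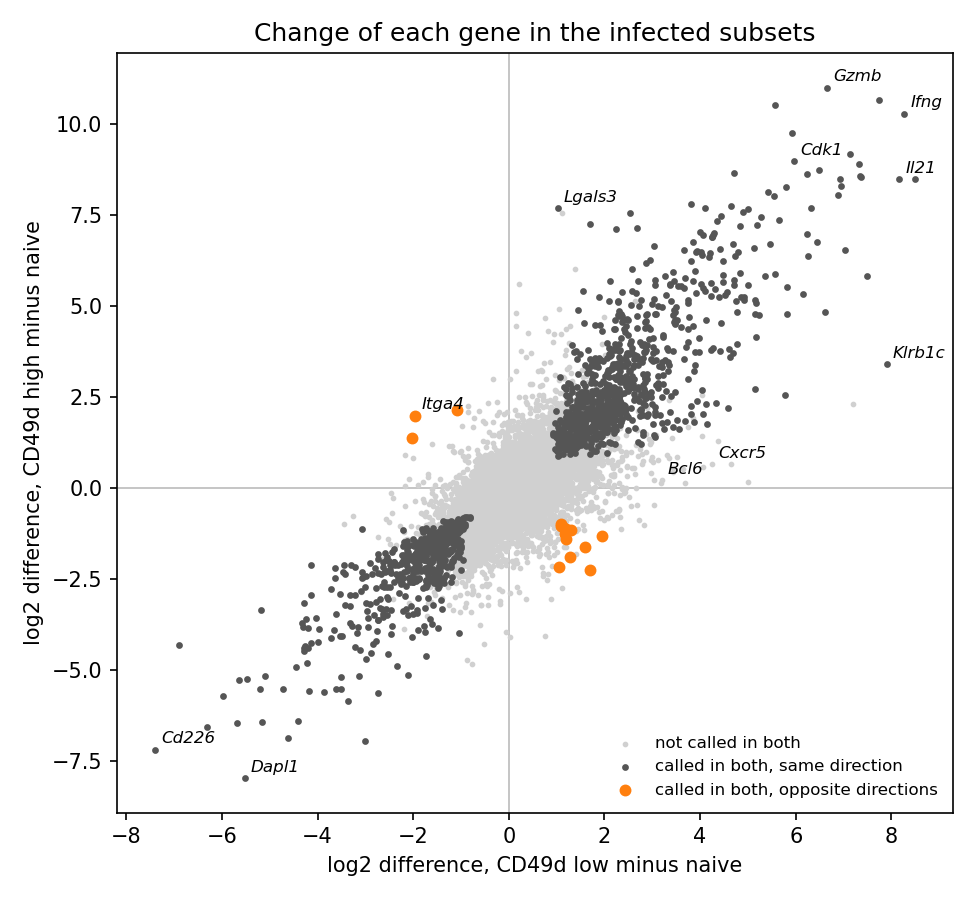
Log2 difference from naive cells of each of 15787 genes in CD49d_lo (x) and CD49d_hi (y), one point per gene, with genes called in both comparisons in dark grey (same direction, 1376) and orange (opposite directions, 15). Gzmb lies at 6.65 in CD49d_lo and 11.01 in CD49d_hi, and Cxcr5 at 4.25 and 0.66.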

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

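All tests on single arrays and on Jchain were chosen after the values were seen, and the test on naive replicate 4 was rewritten after a first form on cell division genes; the counts over other splits of the arrays were planned. In the naive group, with 4 arrays, the gap between 1 array and the others was compared with the group's range for each of the 138 named genes, and chance singles out about 1 in 20. The gap stood out for 7 genes, where chance gives about 6.9. On naive replicate 1, Cd226 was 11.65 where the other naive arrays had 14.25 to 14.6, and Cd4 was 14 against 15.73 to 16. On naive replicate 3, Itga2 was 6.54 against 6.35 to 6.37. On naive replicate 4, Il4 was 6.53 against 4.84 to 4.93, Gpm6b 12.35 against 6.39 to 6.84, Btla 11.22 against 10.05 to 10.25, and Nt5e 9.86 against 6.77 to 7.19.

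The 4 genes that were high on naive replicate 4 were all higher in CD49d_lo than in naive cells. A share of cells like CD49d_lo would need to be 6.17% for Il4 and 61.5% for Nt5e, on the assumption that signals add linearly. Over the 59 other genes that were at least 5 log2 units higher in CD49d_lo, 51 were higher on naive replicate 4, with a median deviation of 1.15 (95% interval 0.80 to 1.59) where even the lowest share would give 2.23. That interval came from a bootstrap of 2000 draws over genes of 1 array. Such genes are not independent, and the interval does not measure the variation between arrays. Ifng deviated by 0.48 against 4.43. These values argue against cells like CD49d_lo as the whole source, while a smaller share for the wider lift could not be excluded. Cells like CD49d_hi are excluded as the source of all 4 genes, because 3 of the 4 lay above the CD49d_hi mean. A smaller share of such cells could not be excluded for Il4 (6.53 against a CD49d_hi mean of 10.43) or for the wider lift. No biological explanation was tested for a single array.

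CD49d_hi replicate 2 stood apart from the other CD49d_hi arrays. Its deviations from them fell with their level, with a slope of -0.11 where the next lowest array, naive replicate 1, had -0.066, so a compressed signal range on that array may account for part of the distance. Cells of another type were not excluded: the highest median deviation of a marker list of another cell type was 0.83, for 5 platelet genes, among them Pf4 (6.91 against 5.6 and 4.67) and Gp9 (8.34 against 7.70 and 7.26). The sort on CD45.1, CD11a and CD49d would remove most such cells. No biological explanation was tested for a single array.

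Jchain was higher in CD49d_hi than in CD49d_lo, with 9.89, 9.06 and 11.56 against 4.80, 4.99 and 4.47. Plasma cells in the CD49d_hi samples are a possible explanation that cannot be told apart from expression by the T cells: 0 of the other plasma cell markers that T cells do not express passed the test, but Mzb1 had 2.25 ± 0.59 (limma adjusted p = 0.061; 0.0163 without CD49d_hi replicate 2) and was highest, at 7.92, on the array with the highest Jchain. Sdc1 had -0.00, Derl3 0.29 and Tnfrsf17 0.11, all at low signal, and immunoglobulin constant genes were not analysed here. Of the B cell list, H2-Aa, H2-Ab1 and H2-Eb1 were higher on each CD49d_hi than on each CD49d_lo array. H2-Eb1 was highest, at 8.63, on the array with the highest Jchain. Past the test over all genes, 0 of the 14 tested B cell genes were higher and 1 was lower, and naive arrays had H2-Eb1 at 5.40 to 6.96. The sort on CD45.1 and CD11a would remove plasma cells of the recipient mice. Expression by CD49d_hi cells themselves, which the groups allow, stays open as well.

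For 15 genes both infected subsets changed against naive cells in the limma test but in opposite directions, where splits of the naive arrays gave 1 to 16 such genes. Only Arhgef4 kept both calls in each of the 10 fits that leave out 1 array, and the calls against naive cells were both kept in 8 fits for Itga4, 5 for Calcoco1, 2 for Cldn10, 1 for Clk1, 6 for Ifngr1 and 0 for Mink1. A difference between the subsets follows from such a selection, and it held for all 15 in each of the 10 fits. Those higher in CD49d_hi were Itga4 (3.96), the sorted protein's own gene, Anxa6 (3.42) and Ifngr1, a chain of the interferon gamma receptor (3.25). Higher in CD49d_lo were Calcoco1 (-3.95), Cldn10 (-3.26), Clk1 (-3.22), Tnfrsf26 (-3.22), Pard6g (-3.16), Ppox (-2.59), Ddb2 (-2.45), Arhgef4 (-2.44), Man2a2 (-2.31), Slc25a42 (-2.23), Fnbp4 (-2.13) and Mink1 (-2.07).

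Other splits of the arrays were counted for each comparison. For CD49d_hi against naive, 1 of the 35 splits of the 7 arrays, the real one, gave 2843 genes, and the highest other gave 313. For CD49d_lo against naive it was also 1 of 35, with 1915 genes and 338 for the highest other. This is the smallest share that 35 splits can give, so chance is unlikely but not excluded. Splits that mix the groups hold the real difference in their spread, which lowers their counts. For CD49d_hi against CD49d_lo the 10 splits are too few, with 532 genes in the real split and 64 in the highest other, and 1 split reached the real value.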

How the results depend on the processing

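The fits without CD49d_hi replicate 2 and naive replicate 1, and without these and naive replicate 4, were chosen after seeing the data. No result changed its direction past a threshold. Of the gene counts, 180 of the values under alternatives lay within 1.5 times the main value and 27 did not; of the values for named genes, 5369 kept their side of the threshold, 230 lost it and 7 gained it; of those for lists, 1600 kept it, 59 lost it and 69 gained it. Array weights (0.318 for CD49d_hi replicate 2) gave 3499 genes for CD49d_lo against naive (2104 higher, 1395 lower) and 1354 for CD49d_hi against CD49d_lo (656 and 698). Without CD49d_hi replicate 2 and naive replicate 1, 990 genes were lower in CD49d_lo than naive and 389 higher in CD49d_hi than CD49d_lo, and 414 of the last without naive replicate 4 as well. Leaving out 1 array gave 2021 to 2786 genes for CD49d_hi against naive (1058 to 1755 higher, 963 to 1317 lower), 907 to 2348 for CD49d_lo against naive (606 to 1533 and 301 to 815) and 255 to 729 for CD49d_hi against CD49d_lo (115 to 310 and 135 to 419), with 15 to 18, 16 to 21 and 11 to 16 lists and 743 to 1612 genes changed alike in both subsets. Fewer arrays lower the counts by construction, but some counts rose. CD49d_lo against naive gave 2348 genes without CD49d_hi replicate 2 and 2085 without CD49d_hi replicate 3. CD49d_hi against CD49d_lo gave 729 without naive replicate 1. An array outside a comparison leaves its differences unchanged, so these rises come from a smaller estimated spread. CD49d_lo against naive gave 1969 without naive replicate 1, and the cause of that rise was not tested. All 10 fits kept 81 of the 91, 66 of the 78 and 34 of the 54 calls for named genes. With an estimated correlation 11 lists passed for CD49d_hi against naive, 12 for CD49d_lo against naive and 5 for CD49d_hi against CD49d_lo, and fry in either direction, a test against no change and not against other genes, gave 30 for CD49d_hi and 29 for CD49d_lo against naive. Splitting the naive arrays left 723 to 796 genes changed alike, with fewer arrays in each comparison. The replicate number as a block gave 1243 genes for CD49d_lo against naive, of which 404 were lower. Naive replicate 4 is alone in its block, so that fit also leaves this array out in effect. Leaving it out without a block gave 1763 genes, of which 620 were lower. With that block the TCR-induced early gene list gave an adjusted p of 0.119 for CD49d_lo against naive, and the cell handling list 0.00404 for CD49d_hi and 0.0221 for CD49d_lo against naive. Both values of the cell handling list assume a correlation of 0.01, where its estimate without the block was 0.838. The B cell list gave 0.0451 for CD49d_lo against naive and ribosomal proteins 0.0612 for CD49d_hi against CD49d_lo. Whether the numbers pair the samples could not be told. The deviations of the infected arrays with the same number correlated at -0.155, -0.0063 and -0.499, and those with different numbers at -0.292 to 0.395. Deviations from a mean of 3 arrays depend on each other, so these correlations cannot decide it. Signal over background limits what low genes show, since no detection calls were used, and the number of arrays limits calls below a log2 difference of 2.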

Other observations

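Gene families outside the fixed lists were looked at after their values were seen. Of 55 histone genes tested, which dividing cells transcribe during DNA replication, 47 were higher in CD49d_hi and 34 in CD49d_lo than in naive cells, and none was lower, with medians of 4.62 and 2.36 on the log2 scale that no other scaling turned. H3c8 rose by 7.59 ± 0.41 in CD49d_hi and by 4.90 ± 0.41 in CD49d_lo (SE; limma adjusted p = 2.12e-07 and 1.34e-05). Between the subsets 24 were higher in CD49d_hi and none was lower, with H3c8 at 2.68 and H1f5, a linker histone, at 2.69. The 24 became 6 without CD49d_hi replicate 1, 13 without CD49d_hi replicate 2, 5 without CD49d_lo replicate 1 and 4 without CD49d_lo replicate 2, and 16 without naive replicate 3, with 30 the highest, without naive replicate 1. Histone genes resemble each other in sequence, and shared signal between their probe sets was not tested.

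Single genes of other families, also chosen after their values were seen, changed. Of 10 genes of S100 proteins, which bind calcium, 5 rose in CD49d_hi against naive cells and none fell, with S100a4 at 7.16 ± 0.62, S100a6 at 6.28 and S100a10 at 3.78. In CD49d_lo 4 of the 10 rose and none fell, S100a4, S100a6, S100a10 and S100a11, and 1 without CD49d_lo replicate 1 or CD49d_lo replicate 2. Between the subsets 2 of the 10 differed, a count that was 3 without naive replicate 1, 3 or 4 and 1 without any other array, and S100a4 was higher in CD49d_hi than in CD49d_lo by 4.47 ± 0.67 (limma adjusted p = 0.00329; at most 0.0176 with 1 array left out). Of 7 galectins, which bind sugars on cell surfaces, Lgals1 and Lgals3 rose and Lgals8 fell in CD49d_hi against naive cells, with a median of 0.06, and Lgals1 and Lgals3 were higher in CD49d_hi than in CD49d_lo. Lgals1 was higher by 3.26 ± 0.62 (0.0123), a call that ended without CD49d_hi replicate 1, CD49d_lo replicate 1 or CD49d_lo replicate 3 (0.00103 to 0.051). Of the 10 annexins, Anxa2 and Anxa6 were higher in CD49d_hi than in CD49d_lo, both with no call lost in the 10 fits that leave out 1 array. Other families were examined as well. Of 6 guanylate-binding proteins 3 were higher in CD49d_hi than in CD49d_lo, and 0 without CD49d_hi replicate 1. Between the subsets 1 of 17 killer cell lectin-like receptors and 1 of 10 Toll-like receptors were lower in CD49d_hi and none was higher, and 0 of 17 semaphorins differed.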
